A study of Mus musculus with 6 samples.

How the data were processed

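ATAC-seq libraries from sorted mouse LT-HSCs (lineage-negative, Sca1- and cKit-positive, CD34- and Flt3-negative) were compared between 3 unconfined and 3 confined samples. The series' design text calls the samples biological replicates. It does not say whether each came from a separate animal. The p-values of single peaks and of group means measure the spread between these samples. Those of the gene list test camera set a list against the other tested peaks, and those of chromosome correlations come from shuffled chromosomes. The authors deposited one table of raw counts per peak for all 6 samples, with peak coordinates. Per the submitters' processing notes, SAMtools 1.14, R 4.2.0, featureCounts and the mm10 build were used. The roles of these tools, the aligner, the peak caller, duplicate removal, any shift of reads for the transposase, and the samples used for peak calling are not given in the sources used here. If peaks were called mainly from the deeper unconfined libraries, sites open only in confined cells would be missing from the table. All peaks were 700 bp wide.

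Peaks were assigned to genes with the RefSeq genes of GRCm38.p6, the assembly also called mm10. The annotation used here gives the start and end of each gene but no strand and no exons. The test planned on transcription start sites was therefore run on peaks whose midpoint lies within 1 kb of either end of a protein-coding gene (11273 peaks), and these are called gene-end peaks and not promoters. Exon, intron and UTR positions are not given for the same reason. With genes moved by 200 kb, 5.43% of peaks lay that close to a gene end, against 26.4% as annotated. For gene lists, each peak was linked to the gene with the nearest end within 50 kb. Of 481 list entries, 478 matched a gene.

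Peaks were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, group as the only term, Benjamini-Hochberg adjustment). The filter kept 9084 of 42632 peaks. It asks for a CPM of about 31.0 in at least 3 libraries, so a peak can enter by being high in one group alone: 430 of the 526 higher peaks reached it in 3 confined and at most 1 unconfined library. Tested peaks held 50.2%, 43.2% and 51.2% of counts in unconfined libraries 1 to 3 and 34.8%, 24.2% and 23.6% in confined ones. CPM of named peaks are TMM-scaled over tested peaks; library shares use all peaks. A floor of 3 counts corresponds to 9.84, 2.44 and 3.05 CPM over all peaks in unconfined libraries and 8.80, 13.6 and 23.4 CPM in confined ones. Correlations used log2(CPM + 1). The fit was tested on simulated counts for the 9084 peaks: it called 28% of peaks changed 2-fold, 78% of those changed 4-fold, and 4 of 8884 unchanged peaks. A change of 2-fold was therefore mostly not detectable at this depth. Both simulated groups shared the same pooled profile, so the number of unchanged peaks called need not hold for libraries with a more level profile. With confined libraries simulated as a straight-line levelling of the unconfined mean, without change at single peaks, 137 to 256 peaks were called higher and 17 to 84 lower.

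Gene lists (23) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation and with fry beside it. DESeq2 1.42.0 and limma-voom were alternative tests. Single values were compared by exact permutation in SciPy 1.17.1 under Python 3.11.15. Named peaks were chosen by a rule set before the data were examined: among peaks past the threshold and changed in the same direction in all 3 pairs, the 12 with the smallest p in each direction and the 8 gene-end peaks with the smallest p in each direction, up to 4 peaks per list whatever their p, and the peaks of genes named in advance, of which only Klf4 is given here. Groups, tests, gene lists and most alternatives were also set then. Alternatives chosen after seeing the data were confined library 1 as the only confined library, thinning of all libraries to the smallest total, random lists matched on mean log2 CPM and gene-end class, and a filter on mean log2 CPM.

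The labels give each sample an experimental batch number, shared by same-numbered samples of the groups, and the pairing comes from that label. In the counts, deviations from the group means correlated at r = 0.0437, 0.0597 and -0.0470 across peaks for pairs 1, 2 and 3. Differently numbered libraries of the groups gave -0.160 to 0.101. The pairing is therefore by label and was not visible in the data. With few counts per peak in the confined libraries, a shared batch effect could be missed by this check. Each batch holds 1 library of each group.

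Planned tests of 29 sequence motifs and the correction for base composition need the genome sequence, which was not used here, and the width correction has no effect on peaks of equal width. Chromosome Y was not analysed, since no peak lay on it.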

Results

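Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in long-term haematopoietic stem cells (LT-HSCs) sorted from the bone marrow of C57BL/6 mice aged 10 to 16 weeks. Unconfined cells (n = 3 libraries) stayed in suspension for 16 h. Confined cells (n = 3) spent 13 h in suspension and 0.5 h attaching to fibronectin-coated glass, were held for 2 h under a ceiling of 5 µm, and were then detached. The comparison asks how squeezing the cell changes the accessible genome of a stem cell. Attachment and detachment went with confinement in every library, so the groups differ in these steps as well. The deposited table holds raw counts for 42632 peaks of 700 bp each on mm10. Total counts in peaks were 304898, 1229478 and 983863 in unconfined libraries 1 to 3, and 340922, 221390 and 128257 in confined libraries 1 to 3. The median peak held 5, 22 and 15 counts in the unconfined libraries and 7, 5 and 3 in the confined ones, so that a confined value at a single peak often rests on few counts.

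Counts at gene ends made up a smaller part of the confined libraries. Peaks centred within 1 kb of either end of a protein-coding gene, a class that includes promoters, took 40.9% ± 2.25 of the counts in unconfined cells and 26.3% ± 4.06 in confined cells (SD, n = 3 each). This class is 26.4% of all peaks. The share was 41.2% in unconfined library 1 (95% Clopper-Pearson interval 41.0 to 41.4), 38.6% in library 2 (38.5 to 38.7) and 43.1% in library 3 (43.0 to 43.2). It was 31.0% in confined library 1 (30.8 to 31.1), 23.9% in library 2 (23.7 to 24.1) and 24.0% in library 3 (23.7 to 24.2). These intervals cover counting error only. All 3 same-numbered pairs changed in this direction, and the difference of -14.6 percentage points was larger than the spread between replicates (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). With confined library 1 as the only confined library the difference was -9.96 points.

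The difference between high and low peaks was smaller in the confined libraries as well. The 2 measures overlap, since a gene-end peak held on average 1.93 times the counts of another peak in unconfined libraries. The 10% of peaks highest in the other unconfined libraries held 7.46, 4.91 and 8.41 times the counts of the lowest 10% in unconfined libraries 1 to 3. In confined libraries 1 to 3 this ratio was 2.76, 1.12 and 0.990. The group means were 6.93 ± 1.81 and 1.62 ± 0.990 (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). Slopes of peak CPM on unconfined CPM were also taken within each class. In confined library 1 the slope was 0.402 near gene ends and 0.476 elsewhere. It was 0.0817 and 0.0558 in confined library 2, and 0.01002 and 0.00183 in confined library 3. Unconfined libraries gave 0.714 to 1.15 near gene ends and 0.664 to 1.08 elsewhere. Both classes were thus levelled, so the smaller gene-end share does not show a loss particular to gene ends. Over all peaks, the log2 CPM (counts scaled to a common library total) of unconfined libraries correlated with each other at r = 0.676 to 0.824. Confined library 1 correlated with them at r = 0.418 to 0.524, confined library 2 at 0.0243 to 0.05 and confined library 3 at -0.0270 to -0.00727. Confined libraries correlated with each other at r = 0.0194 to 0.0856. These are correlations across peaks, which are not independent replicates. Confined libraries 2 and 3 therefore hold almost none of the peak-to-peak pattern shared by the unconfined libraries, and every gene named below was compared with libraries of this kind in the confined group.

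**Figure D1:**
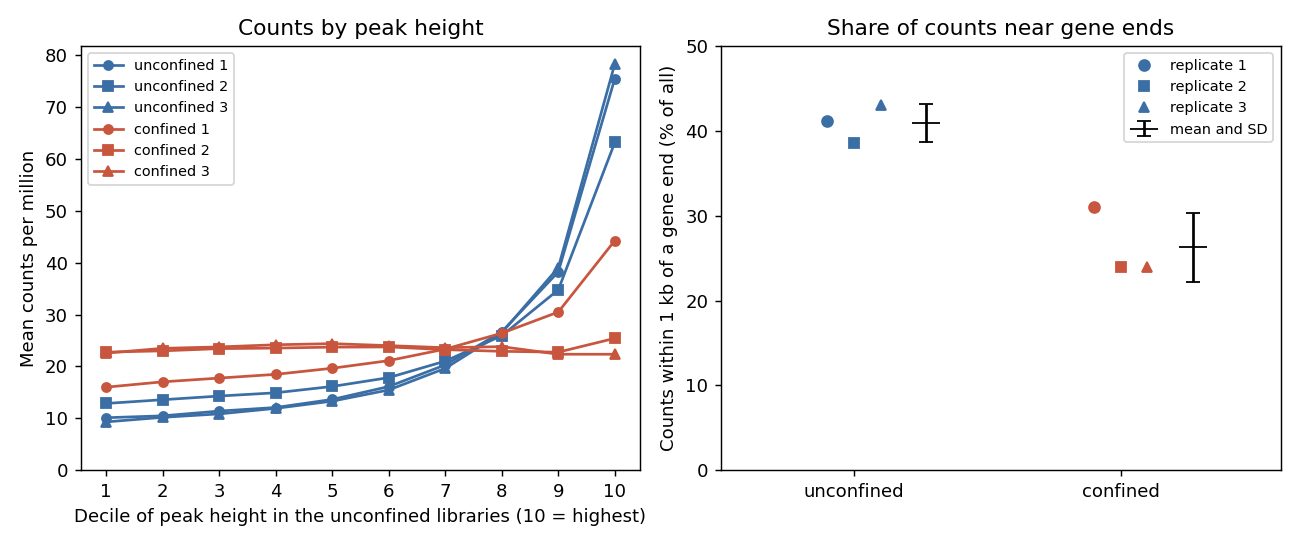
Left, mean CPM per 10% of peaks, ranked by height in the (other) unconfined libraries, for each of the 6 libraries. Right, the percentage of counts in peaks within 1 kb of a gene end, with each library as a point and the mean and SD beside it. The confined libraries lie between 23.9% and 31.0%, below the lowest unconfined library at 38.6%, and the lines of confined libraries 2 and 3 are nearly level.

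Gene-end peaks dominated the peaks that fell in confined cells. The peak at the end of Gbe1, the glycogen branching enzyme, fell from 135 ± 12.3 to 22.2 ± 8.04 CPM (SD, n = 3 each), the change of greatest size in this direction, with a log2 fold change of -2.72 (SE 0.55). Peaks at the ends of Gna11, a G protein alpha subunit, Ywhag, a 14-3-3 protein, Cyth2, an exchange factor for ARF GTPases, and Gatad2a, a subunit of the NuRD complex, fell with log2 fold changes of -1.86, -1.83, -1.88 and -1.73. Peaks that rose lay mostly away from gene ends. A peak inside Ankar rose from 25.6 ± 9.12 to 573 ± 347 CPM, and an intergenic peak whose nearest gene end, 63237 bp away, belongs to Hnmt rose from 74.7 ± 59.0 to 1593 ± 977 CPM (SD, n = 3 each). Here CPM are scaled by TMM over the tested peaks.

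In all, 526 of 9084 tested peaks were higher and 220 lower in confined cells (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p under 0.05). Of the lower peaks, 175 lay within 1 kb of a gene end, against 50 of the higher peaks and 4636 of all tested peaks. The filter shapes this split, since all 220 lower peaks reached its CPM limit in all 3 unconfined libraries and 7 of the 526 higher peaks did. All 220 lower peaks were lower in each of the 3 pairs, and 495 of the 526 higher peaks were higher in each. Among all 9084 tested peaks, 2329 were lower and 1711 higher in each. The calls come from the same libraries, which favours such agreement, so it adds no support. The split depended on scaling: with total counts as the only scaling, which moved the median log2 fold change of all tested peaks from -0.02 to -0.68, 348 peaks were higher and 2286 lower. With the replicate number as a block, 476 peaks were higher and 74 lower. With confined library 1 as the only confined library, the spread comes from the unconfined libraries alone, here and in every later use. There 37847 peaks were tested, so its calls cannot be set against those above. The median log2 fold change there was -0.52 within 1 kb of gene ends and 0.12 elsewhere. When the same number of peaks was chosen by mean log2 CPM, 171 were higher and 71 lower, and 135 and 71 of these had been called in the same direction before. Without unconfined library 1, 2 or 3 the counts of higher and lower peaks were 565 and 766, 672 and 272, and 275 and 76. Without confined library 1, 2 or 3 they were 1696 and 788, 250 and 80, and 873 and 564. These fits tested other sets, of 15977, 11183 and 10728 peaks without an unconfined library and 10622, 13606 and 13092 without a confined one. Of the 526 higher peaks, 222, 286 and 141 were again called higher without unconfined library 1, 2 or 3. Without confined library 1, 2 or 3, 313, 94 and 328 were. Of the 220 lower peaks, 204, 185 and 73, and 180, 61 and 220, were again called lower in the same order.

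Over tested peaks, the median log2 fold change was -0.26 within 1 kb of gene ends and 0.27 elsewhere. Mean log2 CPM near gene ends lay above that of other tested peaks by 0.40 ± 0.06 in unconfined libraries, and the same difference was -0.19 ± 0.14 in confined libraries (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). The medians of both classes are relative to the TMM scaling: with total counts alone they were -0.92 and -0.39, so the second turned negative while the first stayed below it. With 1 library left out, the first ranged from -0.63 to -0.34 and the second from 0.27 to 0.52, both farthest from 0 without unconfined library 1. The medians were -0.58 and 0.30 with no filter and -0.05 and 0.11 with a mean count of at least 50. With all libraries thinned to the smallest total they were -0.09 and 0.18.

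**Figure D2:**
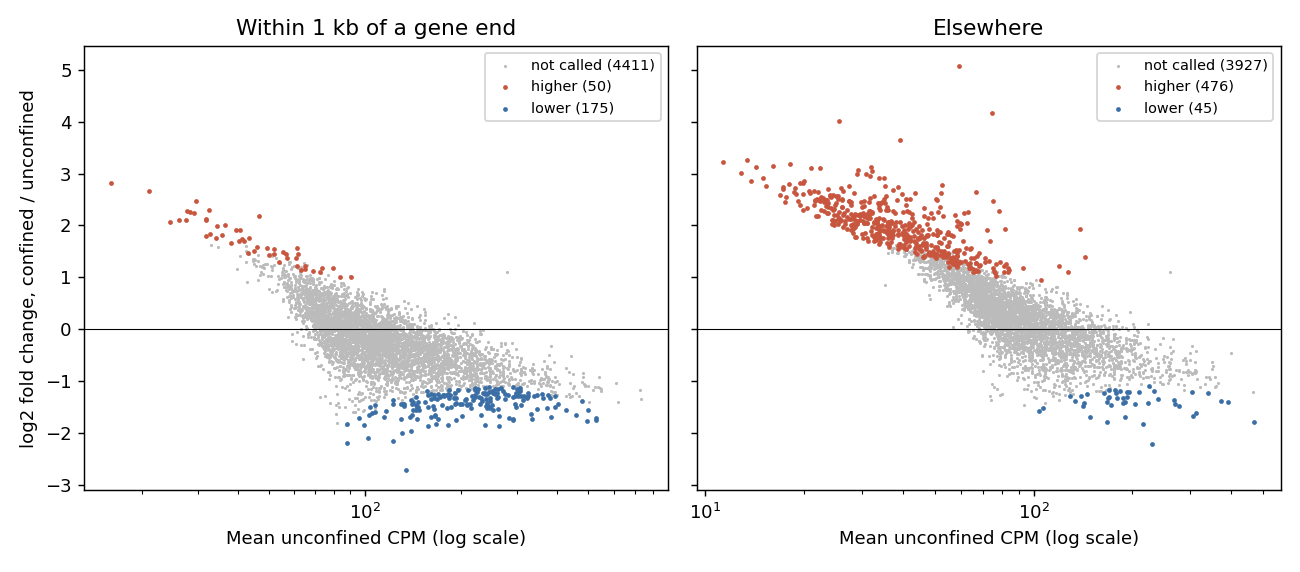
Log2 fold change (confined over unconfined) of each tested peak against its mean unconfined CPM on a log axis, for peaks within 1 kb of a gene end (left) and elsewhere (right), with called peaks in colour. Of the lower peaks, 175 are in the left panel, and 476 of the higher peaks are in the right one. The unconfined mean enters both axes, which by itself gives a downward slope.

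Among the 12 lower peaks with the smallest p, 8 lay within 1 kb of a gene end. The peak on chromosome 16 from 70313866 to 70314565, at the Gbe1 end (gene 70313949 to 70569720), held 22, 65 and 65 counts in unconfined libraries and 2, 1 and 1 in confined ones (edgeR adjusted p = 0.00153). At Klf13, which encodes a Krüppel-like transcription factor, the peak on chromosome 7 from 63938942 to 63939641 lay 376 bp from the gene end and fell from 231 ± 8.72 to 78.4 ± 14.3 CPM (log2 fold change -1.66, SE 0.39, edgeR adjusted p = 0.00582). The remaining gene-end peaks of this set lay at Fam76a and at Cdca3, a regulator of mitotic entry, with log2 fold changes of -1.85 and -1.71. Away from gene ends, peaks in the gene bodies of Tsga10, Stag1, a cohesin subunit, and Mnt, a MAX-binding repressor, fell with log2 fold changes of -1.83, -1.70 and -1.79. A peak 6904 bp from Zfp239, on chromosome 6 from 117879321 to 117880020, had the smallest p in this direction, with 229 ± 11.3 CPM in unconfined and 56.8 ± 21.1 CPM in confined cells (log2 fold change -2.21, SE 0.43, edgeR adjusted p = 0.00110). The edgeR adjusted p of these 12 peaks ranged from 0.00110 to 0.00688.

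Of the 12 higher peaks with the smallest p, none lay within 1 kb of a gene end. The Ankar peak, on chromosome 1 from 72696118 to 72696817 within the gene, held 3, 19 and 10 counts in unconfined and 22, 37 and 27 in confined libraries (log2 fold change 4.02, SE 0.40, edgeR adjusted p = 4.69e-09). The peak nearest Hnmt, on chromosome 2 from 23939325 to 23940024, held 7, 75 and 17 counts in unconfined and 85, 77 and 84 in confined libraries (log2 fold change 4.17, SE 0.52, edgeR adjusted p = 2.12e-06). Of the 12, 3 peaks lay in or near the predicted gene Gm7827 on chromosome 8, between 71130864 and 71175712, with log2 fold changes of 2.28, 2.62 and 2.92. Others lay in the gene bodies of Dnah7b, an axonemal dynein heavy chain (2.65), and Clstn1 (2.49). The rest lay outside genes and were nearest to Pisd, a mitochondrial phosphatidylserine decarboxylase (2.77), the transcription factor gene Batf3 (2.48), Gcnt2 (2.19) and the predicted genes Gm52420 on chromosome X (2.96) and Gm6351 (2.74). The 8 gene-end peaks with the smallest p among those that rose belonged to Rab7, a GTPase of late endosomes, Zfp72, Fabp3, a fatty acid binding protein, Prpf40b, Cnrip1, Gsg1, Akap6 and Acy3. Their log2 fold changes ranged from 2.01 at Gsg1 to 2.81 at Fabp3, where the unconfined libraries held 0, 21 and 4 counts and the confined libraries 12, 12 and 4. None of these 8 was among the peaks tested when peaks were chosen by mean log2 CPM.

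At Klf4, a transcription factor gene, 2 peaks were tested. The Klf4 peak 237 bp from the gene end, on chromosome 4 from 55532363 to 55533062, held 114 ± 19.6 CPM in unconfined and 45.7 ± 12.7 CPM in confined cells (SD, n = 3 each) and did not pass (log2 fold change -1.19, SE 0.45, edgeR adjusted p = 0.0906). It passed with total counts as the only scaling (log2 fold change -1.83, edgeR adjusted p = 0.00717), with loess offsets (-1.43, 0.0473), with no filter (-2.05, 0.0133) and without unconfined library 1 (-1.62, 0.0251). A Klf4 peak inside the gene, from 55530133 to 55530832, rose from 70.9 ± 25.5 to 259 ± 197 CPM (log2 fold change 1.38, SE 0.41, edgeR adjusted p = 0.0265). In confined library 1 alone the direction of that peak turned, with a log2 fold change of -0.41, and with total counts as the only scaling it was 0.74 and did not pass (edgeR adjusted p = 0.154). It also missed the threshold without confined library 2 or 3 or without unconfined library 1 or 2, with log2 fold changes of 1.04, 0.67, 0.89 and 0.98, and with no filter (0.54), DESeq2 (1.79) and limma-voom (1.01).

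**Figure D3:**
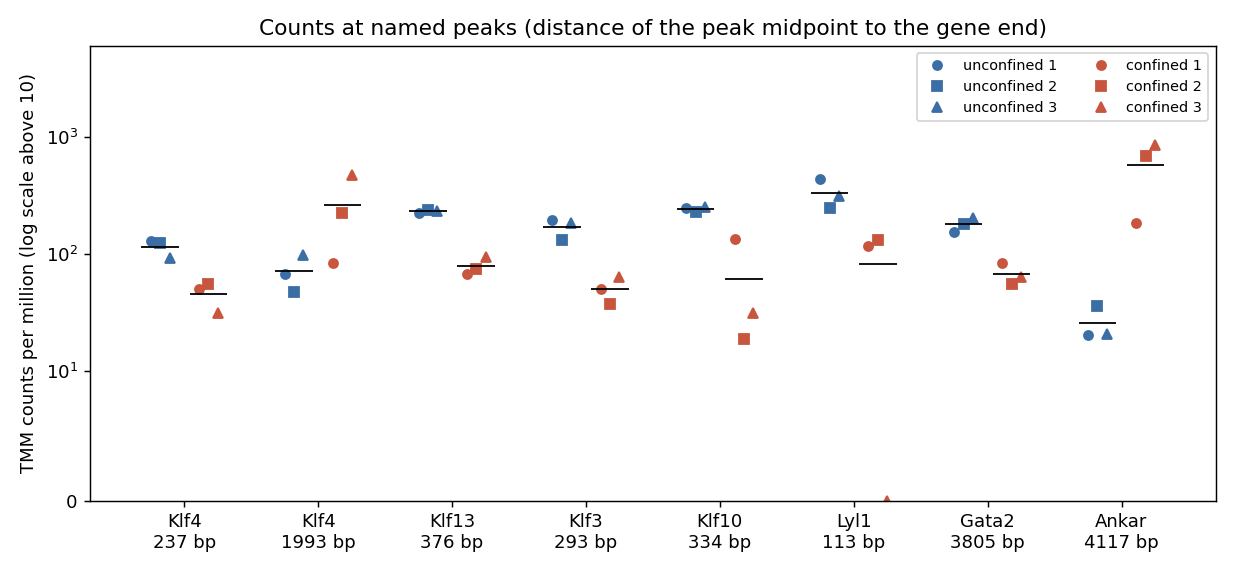
TMM-scaled CPM of each library at 8 named peaks, labelled by nearest gene and distance to the gene end, on an axis that is logarithmic above 10. Points are libraries and bars are group means. At Klf13 the confined mean of 78.4 CPM lies below the unconfined mean of 231, and at Ankar the confined mean of 573 lies above the unconfined mean of 25.6.

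The KLF and SP transcription factor list was the only one of 20 tested gene lists to pass, and its peaks were lower on balance. Of its 22 tested peaks from 15 genes, 3 fell and 1 rose over all peaks, and 7 fell and 1 rose when adjusted over the list alone. The peaks that fell lay at the ends of Klf13, Klf3 (log2 fold change -1.74) and Klf10 (-1.48), and the peak that rose was the one inside Klf4. The median was -0.74 (camera with a preset correlation in limma, adjusted p = 0.0335). No list passed the directional fry test in limma (adjusted p = 0.139 for this list, lowest 0.0757 for the T and NK cell list). The camera call was lost with an estimated correlation (camera in limma, adjusted p = 0.806 with an estimated correlation) and with the replicate block (camera in limma, adjusted p = 0.0541). It was also lost without any 1 of the unconfined libraries (camera in limma, adjusted p = 0.0506, 0.0751 and 0.117 without library 1, 2 and 3), and without confined library 3 (0.273). With loess offsets and the mean log2 CPM filter the medians were -0.44 and -0.61 (camera in limma, adjusted p = 0.0641 and 0.127). With confined library 1 alone, a test on 1 confined library, the median was -0.37 (camera in limma, adjusted p = 0.192). Of its 22 peaks, 12 lay within 1 kb of a gene end. These 12 alone had a median of -1.10 (camera in limma against all tested peaks, adjusted p = 0.000317, and 0.342 with an estimated correlation). All tested gene-end peaks had a median of -0.26 against 0.27 elsewhere, so part of this shift is that of the class. Among 10000 random lists matched on gene-end class and mean log2 CPM, chosen after seeing the data, the list's median lay at percentile 0.04, and 95% of the random medians lay between -0.55 and -0.04.

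Among the lists of the mechanical response given here, none passed (camera in limma, adjusted p = 0.753 for the YAP-TEAD list, 0.886 for the SRF-MRTF and cytoskeletal list, 0.839 for the nuclear envelope and lamina list and 0.839 for the heterochromatin list). In the YAP-TEAD list, 1 of 11 peaks rose, at Ccn2, a matricellular protein gene (2.28), and none fell; 2 rose and 1 fell when adjusted over the list alone. In the SRF-MRTF list, 1 of 19 peaks rose, near the calponin gene Cnn1 (1.40), and 1 fell, at the non-muscle myosin gene Myh9 (-1.27), as when adjusted over the list alone. In the nuclear envelope and lamina list, 2 of 23 rose, inside the nesprin gene Syne3 (1.48) and the nucleoporin gene Nup210 (1.40), as when adjusted over the list alone. In the heterochromatin list, 1 of 17 rose, inside the histone demethylase gene Kdm4b (2.46), also when adjusted over the list alone. In the integrin and adhesion list, 2 of 23 rose, inside the tetraspanin genes Cd9 (2.40) and Cd81 (1.76), also when adjusted over the list alone (camera in limma, adjusted p = 0.598). With the replicate block, the calls at Myh9, Cnn1, Nup210 and Cd81 were lost (edgeR adjusted p = 0.0990, 0.0574, 0.0609 and 0.0502).

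Stem cell identity genes moved in both directions, and the list did not pass (36 peaks, median -0.17, camera in limma, adjusted p = 0.713). Peaks at Lyl1, a basic helix-loop-helix factor, and inside Gata2, a zinc finger factor of stem cell maintenance, fell with log2 fold changes of -1.64 and -1.34, and a peak near Nkx2-3 rose (1.41); the counts were the same when adjusted over the list alone. The Lyl1 peak held 331 ± 96.8 CPM in unconfined and 82.2 ± 71.5 CPM in confined cells (SD, n = 3 each). With the replicate block, the Gata2 call was lost (edgeR adjusted p = 0.0862). In the HSC ageing list, none of 14 peaks passed, over all peaks or when adjusted over the list alone (median 0.36, camera in limma, adjusted p = 0.713). In the cell cycle list, 2 of 22 peaks fell, at the cyclin gene Ccna2 (-1.48) and at Cdk4 (-1.59), also when adjusted over the list alone (camera in limma, adjusted p = 0.713). The Cdk4 call was lost with the replicate block (edgeR adjusted p = 0.108).

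In the stress and signalling lists, single peaks changed and no list passed. In the immediate early list, 1 of 51 peaks rose, near the phosphatase gene Dusp5 (1.97), and 1 fell, near the antiproliferative gene Btg2 (-1.63), as when adjusted over the list alone (camera in limma, adjusted p = 0.829). In the NF-kB list, 1 of 19 peaks fell and 1 rose, and both lay nearest to the chemokine gene Ccl3, 7570 bp (-1.67) and 21 bp (1.46) from its ends; 2 rose and 1 fell when adjusted over the list alone (camera in limma, adjusted p = 0.713). The second Ccl3 peak was higher in 2 of 3 pairs, and in confined library 1 alone its log2 fold change was -0.16. In the p53 and DNA damage list, 1 of 19 peaks rose, near Gadd45g (2.21), also when adjusted over the list alone; the list's median was -0.15 and its mean 0.01 (camera in limma, adjusted p = 0.782). In the heat shock list, 1 of 19 peaks rose, inside the unfolded protein response gene Xbp1 (1.54), and none when adjusted over the list alone (camera in limma, adjusted p = 0.713). In the interferon list, none of 8 peaks passed over all peaks, and 1 rose when adjusted over the list alone (camera in limma, adjusted p = 0.753).

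Marker lists of other cell types gave few calls. A peak near Notch1 rose among 9 peaks of the multipotent and lymphoid progenitor list (2.00), a peak inside Tmcc2 among 6 erythroid peaks (1.77) and a peak inside Tcf7 among 8 peaks of the T and NK cell list (2.05). When adjusted over the list alone, 1, 2 and 1 peaks rose in these lists, and none of the lists passed (camera in limma, adjusted p = 0.713, 0.629 and 0.598). None of 10 megakaryocyte and 8 granulocyte and monocyte peaks passed, over all peaks or when adjusted over the list alone (camera in limma, adjusted p = 0.753 and 0.713). Their medians were 0.11 and -0.05, and the direction of the camera test was down for both. The B cell, mast cell and endothelial lists had fewer than 3 tested peaks and were not tested as lists.

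Several of these single calls in lists depended on the filter or the scaling. The peaks that rose at Ccn2, Cnn1, Kdm4b, Cd9, Cd81, Gadd45g, Xbp1, Notch1, Tmcc2 and Tcf7 were not among those tested when peaks were chosen by mean log2 CPM. With that filter, the calls at Nup210, Nkx2-3, the second Ccl3 peak, Myh9, Gata2 and Cdk4 were lost (edgeR adjusted p = 0.0542, 0.0510, 0.0516, 0.0651, 0.0529 and 0.0691). With total counts as the only scaling, the calls at Syne3, Nup210, Nkx2-3, the second Ccl3 peak, Cnn1, Xbp1 and Tmcc2 were lost (edgeR adjusted p = 0.0869, 0.133, 0.133, 0.119, 0.161, 0.116 and 0.0531).

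Along the genome, chromosome 2 took 7.33% ± 0.135 of counts in unconfined and 8.38% ± 0.840 in confined cells (SD, n = 3 each). The confined values were 7.51%, 8.45% and 9.19%. Chromosome 7 took 7.65% ± 0.138 and 6.80% ± 0.796, with 5.88% in confined library 3. Neither passed over 20 chromosomes (two-sided exact permutation p = 0.1 each, the smallest possible, adjusted p = 0.286). Chromosomes 4, 6, 11, 13 and 14 had the same exact permutation p; chromosome 6, for example, took 5.37% ± 0.0849 and 5.70% ± 0.0725. Chromosome X, with 867 peaks, took 1.90% ± 0.0331 and 2.12% ± 0.259 (two-sided exact permutation p = 0.4, adjusted p = 0.889).

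**Figure D4:**
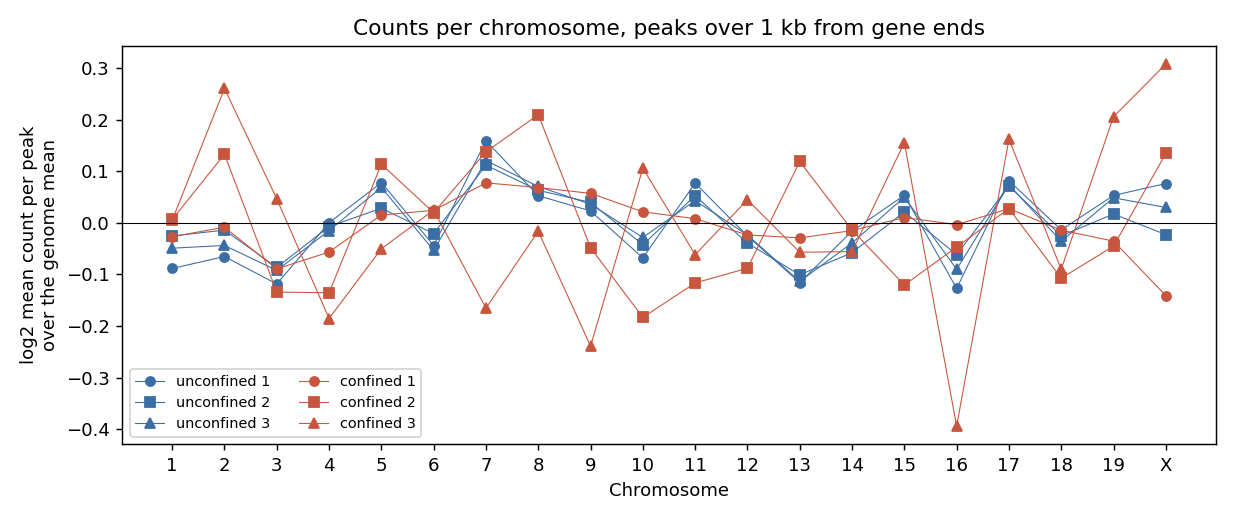
Log2 mean count per peak on each chromosome over the genome mean of the same library, for peaks more than 1 kb from gene ends. Each point is a library. Confined library 3 lies at -0.39 on chromosome 16 and at 0.31 on chromosome X.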

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

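Alternatives using confined library 1 as the only confined library, thinned libraries or the mean log2 CPM filter were chosen after the data were seen; for the difference between gene-end and other peaks, all alternatives but total counts, RLE and loess were as well. Higher peaks numbered 348 with total counts, 293 with loess offsets, 3 with a mean count of at least 50 (439 peaks tested), 3 with thinned libraries (812 tested) and 171 with the mean log2 CPM filter. They ranged from 250 to 1696 with 1 library left out (10622 to 15977 tested). Lower peaks numbered 74 with the replicate block, 2286 with total counts, 1821 with no filter (42632 tested), 0 with a mean count of at least 50, 75 with DESeq2, 7 with confined library 1 alone, 0 with thinned libraries and 71 with the mean log2 CPM filter, and ranged from 76 to 788 with 1 library left out. At a mean count of at least 50, edgeR gave an unadjusted p under 0.05 to 36 of 439 peaks, and with thinned libraries to 82 of 812. In the main fit it was 2278 of 9084, so the share of such peaks was also smaller in the 2 small fits. No other tool was run there. The cause of these low counts and of the other changes was not tested. RLE, upper quartile, limma-voom and autosomes only moved neither count by over 1.5 times (467 to 783 higher, 217 to 254 lower).

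The difference in the gene-end share ranged from -17.0 to -13.5 points with 1 library left out, was -14.3 and -14.8 with windows of 500 bp and 2 kb, and was -9.96 with confined library 1 alone. The median of gene-end peaks minus that of other tested peaks, -0.52, was -0.89 with no filter, -0.15 with a mean count of at least 50 and -0.27 with thinned libraries, and ranged from -1.15 to -0.64 with 1 library left out. It was -0.53, -0.53 and -0.42 with total counts, RLE and loess offsets. The cause was not tested. The number of lists past the threshold, 1, was 2 with gene-end peaks only, 0 with the replicate block, 0 with loess offsets, 0 with the mean log2 CPM filter and 0 with confined library 1 alone, and ranged from 0 to 1 with 1 library left out.

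For 61 named peaks, 801 of 1024 values under alternatives kept direction and side of the threshold, 216 lost the threshold, 5 gained it and 2 reversed, the intragenic Klf4 peak (-0.41) and the second Ccl3 peak (-0.16), both with confined library 1 alone; the cause was not tested. Among peaks named in the text, the replicate block changed no call but those given beside the results. Motifs, the correction for base composition, and the block combined with it were not run, and the width correction has no effect on peaks of 1 width.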

Other observations

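All tests reported here were chosen only after the results they bear on had been seen. Higher peaks gathered at a few clusters of related genes. On chromosome 7, between 20149568 and 20747196, 15 of 18 tested peaks were higher in confined cells, most of them nearest to vomeronasal receptor genes such as Vmn1r93 and Vmn1r101 and the others to Gm10668 and Gm10670. On chromosome 5, all 7 tested peaks between 94008805 and 94992747 were higher, nearest to genes that include Pramel40 and Pramel44, and all 6 between 95030750 and 95675297, nearest to Pramel45, Pramel47 or Gm7982. On chromosome 8, 10 of the 24 tested peaks in a window of 1 Mb were higher; these 10 are all the tested peaks between 71092401 and 71195258 and lie nearest to Gm7827. Windows of 1 Mb with at least 4 higher peaks numbered 11, against a mean of 3.72 and a maximum of 11 in 1000 shuffles of the calls over tested peaks.

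Among the 500 peaks highest in unconfined cells, 2 stood far above the others in confined library 3, with 421 and 398 CPM over all peaks against a median of 15.6. In confined library 2 they held 90.3 and 81.3 CPM, and a peak near Fmc1 also held 81.3. The peaks at 421 and 398 CPM overlap genes of 7SL RNA, the RNA of the signal recognition particle: Rn7s2 (chromosome 12, 69361199 to 69361898) and Rn7s1 (69158970 to 69159669). Confined library 3 held 54 and 51 counts there. A peak on chromosome 17 from 4626032 to 4626731, 367916 bp from Arid1b, held 5, 5 and 66 counts in unconfined and 8, 59 and 193 in confined libraries, with the highest count of each group in batch 3.

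The level profile of the confined libraries was set against lower depth, an even background and confinement itself. Lower depth as the cause is argued against: unconfined libraries thinned to the confined totals kept a mean r of at least 0.441 with the other unconfined libraries, where confined libraries 2 and 3 reached 0.0401. Confined library 1 reached 0.466 to 0.519. Thinned to at most its total, the unconfined libraries kept 0.616 to 0.684. For confined library 1, the scatter around a straight line through unconfined CPM was 1.43 times that of counting. Unconfined libraries thinned to at most its total gave 1.31 to 1.91. Diluted with a simulated, perfectly even background to its slope, they gave 1.06 to 1.11. A perfectly even background added to an unconfined-like profile thus left less scatter than was seen in this library. An uneven background was not tested and stays open. In confined libraries 2 and 3, with slopes of 0.0396 and -0.0161 on unconfined CPM, this scatter was 1.57 and 1.95 times that of counting. A perfectly even background with counting noise alone would not exceed counting, so these values argue against it as the whole profile of these libraries. An uneven background was not tested there and stays open as well. Evening out of accessibility by confinement cannot be told apart from attachment or detachment, which went with the group. The highest slope of a confined library on unconfined CPM was 0.416, in library 1.

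Chromosome levels varied most in confined libraries 2 and 3. Counting noise and peak-to-peak spread are argued against, since the SD of log2 chromosome levels was 0.115 and 0.173 against maxima of 0.0347 and 0.0597 in 1000 shuffles; unconfined libraries, at 0.0551 to 0.0802, also exceeded their shuffles, by less. A bias shared by level libraries, such as mappability or base composition, is argued against as the whole cause, since the levels of these libraries correlated at r = 0.153 over 20 chromosomes (permutation p = 0.524, 95% interval -0.311 to 0.558; Spearman correlation 0.147, permutation p = 0.533; r = 0.289 without the 2 farthest chromosomes). Unequal sampling of whole chromosomes, as from few nuclei, stays open. In confined libraries 2 and 3, the levels of the first and second parts of each chromosome correlated at r = 0.825 and 0.725 over 20 chromosomes (permutation p = 2e-05 and 0.00032, adjusted over 6 libraries 0.00012 and 0.00096). The Spearman correlation was 0.832 and 0.779 (permutation p = 2e-05 and 0.00014). Deviations of these parts from the unconfined libraries correlated at 0.383 and 0.587, against 0.473, 0.509 and -0.385 in the unconfined libraries. The SD of these deviations in the first parts was 0.133 and 0.189, against 0.0329, 0.0282 and 0.0236, so these r describe shifts of unlike size. Taking unconfined levels from libraries that hardly hold the unconfined pattern can itself lower r, so this comparison decides nothing. Whether confinement contributes was not tested, and the r in confined library 1 was 0.518 with an SD of 0.0514.

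The higher peaks were set against the count filter and multi-copy sequence. The filter as the whole cause is argued against, since 135 of the 526 were called higher also when peaks were chosen by mean log2 CPM. Only 195 of the 526 were tested there, so the others could not be checked. Simulated libraries that were only levelled gave 137 to 256 higher and 17 to 84 lower peaks with the first filter. With the second they gave 3 to 12 higher and 0 to 5 lower. These simulations held counting noise only. The scatter of confined libraries 1 to 3 around the line was 1.43, 1.57 and 1.95 times that of counting, so the simulated numbers need not hold for them. Reads from multi-copy sequence stay open: away from gene ends, 68 of 476 higher peaks and 94 of 3972 others lay nearest to a predicted Gm gene or a gene of 7 listed families (odds ratio 6.88; 24 and 14 without the Gm genes, odds ratio 15.0), but the list was made after the higher peaks had been seen, so these values decide nothing. Of 8 tested peaks nearest to olfactory receptor genes, 0 were higher. For the calls as a whole, 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 746 peaks and the highest of the others 2, but every other split mixes the groups on both sides. The group difference then adds to the spread within each side, so few calls are likely there and this contrast decides nothing.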
